A study of Mus musculus with 13 samples.

How the data were processed

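Gene expression was measured on Affymetrix mouse genome arrays in 13 samples of UG26-1B6, a stromal cell clone derived from the urogenital ridge of midgestation mouse embryos. Per the labels' protocols, stroma was grown to confluence, irradiated with 30 Gy and seeded with LSK cells, a bone marrow fraction that lacks lineage markers, carries Sca-1 and c-Kit and is rich in haematopoietic stem and progenitor cells. Co-cultures were kept for 1, 2 or 3 days. Day 0 cells were collected by trypsinisation, and a medium control was harvested 24 h after a change of medium. Whether the day 0 and medium control cells were irradiated, and how stroma was separated from LSK cells at harvest, is not given in the sources used here. Per the labels' protocols, RNA was isolated with a column kit for small samples and amplified to biotin-labelled antisense RNA. Sample titles call the replicates biological, while the series' design text calls them technical, so p-values measure only the spread between these samples.

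The deposited values are on a log2 scale, as read from their range of 2.28 to 15.7, with 1 value per probe set and array. RMA and GCRMA are both named, per the submitters' processing notes, without a version or a statement of which values each made. The table was used as deposited, with no further scaling. A shared lowest value of 2.28 took up 31.7% to 44.5% of an array's probe sets, and some probe sets had a higher lowest value of their own. A difference from a group that sat wholly at such a value, or wholly under the filter value of 2.38, is treated as a lower bound and, where it passed, is written as at least. Scanner files were not used here. The number of arrays limits the precision of every value.

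Of 45101 probe sets, 64 were controls and stayed out of the gene tests. In the platform annotation 34958 probe sets had 1 gene symbol, 932 had several and 9211 had none. Among those with 1 symbol, 34754 matched the RefSeq gene table and 204 did not, and no symbol was changed. A probe set entered if its value was above the pooled median of 2.38 in at least 2 arrays, which 25216 did. Each gene was represented by its probe set with exactly 1 symbol and the highest mean over all arrays, giving 12205 genes, of which 5467 had several probe sets past the filter.

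Arrays were grouped by their titles. All 13 entered a single fit with a mean per group in limma 3.58.1 under R 4.3.3 (lmFit, contrasts, eBayes), so that groups of 2 and 3 arrays shared an estimate of each gene's spread. Adjusted p-values are Benjamini-Hochberg values over the 12205 genes of a comparison, with a threshold of 0.05. Changes are log2 differences of group means ± standard error. Figures were drawn with Python 3.11.15. Each of the 7 comparisons also tested 25 gene lists with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with limma's fry, adjusted over the 25 lists.

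The lists were the CCN family, TGF-beta and BMP signalling, Wnt signalling, haematopoietic niche factors, inflammatory cytokines and NF-kB targets, interferon response, extracellular matrix, matrix proteases and inhibitors, proliferation, p53 targets, immediate early response, cholesterol biosynthesis, glycolysis and hypoxia response, unfolded protein and amino acid response, smooth muscle, adipocyte lineage, osteoblast and chondrocyte lineage and oxidative stress response. Markers of other cells that a harvested well could hold formed the lists for haematopoietic stem and progenitor cells, myeloid, mast, erythroid and megakaryocyte, lymphoid, endothelial and epithelial cells. The groups, the tests, the 7 comparisons, the lists, most alternatives and the rule for named genes were fixed before the data were examined.

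Named genes followed that rule. In each comparison the 8 largest rises and 8 largest falls among genes past the threshold with non-overlapping groups were taken, or 4 and 4 between days of co-culture. For each described list, up to 4 members with the largest change past the threshold were added, or up to 2 as values where none passed. Ccn2 (formerly Ctgf), Wnt5a, Sfrp1, Cxcl12, Kitl, Vcam1, Cdkn1a, Mki67, Col1a1, Ptprc, Kit and Cd34 were always taken. The text prints a part of these genes with full statistics. Every gene past the threshold, in every comparison, had all arrays of one group above all arrays of the other.

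The alternatives left out the filter or used other filters, rescaled the arrays by quantiles or by medians, averaged or kept all probe sets of a gene, and changed the variance model. Further alternatives weighted the arrays, fitted only the compared groups, used the replicate number as a block, or left out each array in turn. A stricter filter, centring on the measured probe sets, a poly-A spike-in covariate and the removal of doubted arrays were added after the data had been seen. The test of each comparison was tested on simulated data of 13 arrays and 12205 genes, with 200 genes changed, in 5 runs. For day 1 co-culture against the medium control it recovered 12.5%, 35.5% and 59.7% of genes changed 2-, 4- and 8-fold, with 2.98% false calls. For day 2 of co-culture against day 1 the values were 13.7%, 45.7% and 64.5%, with 5.07% false calls. In fits without day 2 replicate 1 the false calls were 6.93% and 4.82% in these 2 comparisons. They were 5.6%, 6.36%, 6.98% and 6.18% for the medium control and days 1, 2 and 3 against day 0. Simulated noise was drawn independently for each gene.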

Results

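Stroma of the clone UG26-1B6 was profiled in 5 groups: cells before co-culture (day 0, n = 3), a medium control 24 h after a change of medium (n = 2), and stroma after 1, 2 and 3 days with LSK cells (n = 3, 3 and 2). The series asks how stroma-derived factors maintain haematopoietic stem cells, and the medium control is matched in time to day 1 of co-culture. Levels are log2 values, given as mean ± SD over the arrays of a group, and changes carry their standard error.

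Some genes of blood cells were higher in co-culture. Ptprc, which encodes the pan-leukocyte phosphatase CD45, lay at the lowest value on all 5 day 0 and medium arrays. It measured 2.69 to 4.13 on the day 1 arrays, 6.94 to 10.93 on day 2 and 5.34 and 9.18 on day 3. Mpo, the myeloperoxidase of granulocyte precursors, likewise lay at its lowest value without LSK cells and reached 12.36 on day 2 replicate 1. Cd34, Ikzf1, Irf8, Vwf and Slc4a1, all but Cd34 picked after their values were seen, lay at 7.75 to 9.39 on day 2 replicate 1 and at most at 5.59 on the other 12 arrays. Of 45 measured stem, progenitor and myeloid markers, 9 lay above 5 at day 0. On day 2 replicate 1, 36 of them lay more than 2-fold above the day 0 mean, and 27 of 40 matrix genes lay more than 2-fold below it. Kit, which encodes the receptor used to sort LSK cells, stayed between 2.28 and 2.38 on every array and was not tested. Spike-in RNAs with poly-A tails, usually added so that their signal is larger where less sample RNA is present, averaged 6.95 ± 1.54 at day 0 and 4.79 ± 0.15 in the medium control. They averaged 11.38 ± 0.98, 11.55 ± 2.43 and 12.96 ± 1.41 on days 1, 2 and 3 of co-culture. The amounts added, and whether they were scaled to the sample RNA, are not given in the sources used here, so the signal is an uncertain reading of RNA input. The 3' probe sets of Gapdh exceeded its 5' probe set by 8.96 on day 2 replicate 1 and by 5.79 on day 3 replicate 2, against at most 3.82 at day 0 and in the medium control. Day 2 replicate 1 correlated across genes at most at 0.785 with any other array, while the 2 medium arrays correlated at 0.996. Genes are not independent replicates in such correlations.

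**Figure D1:**
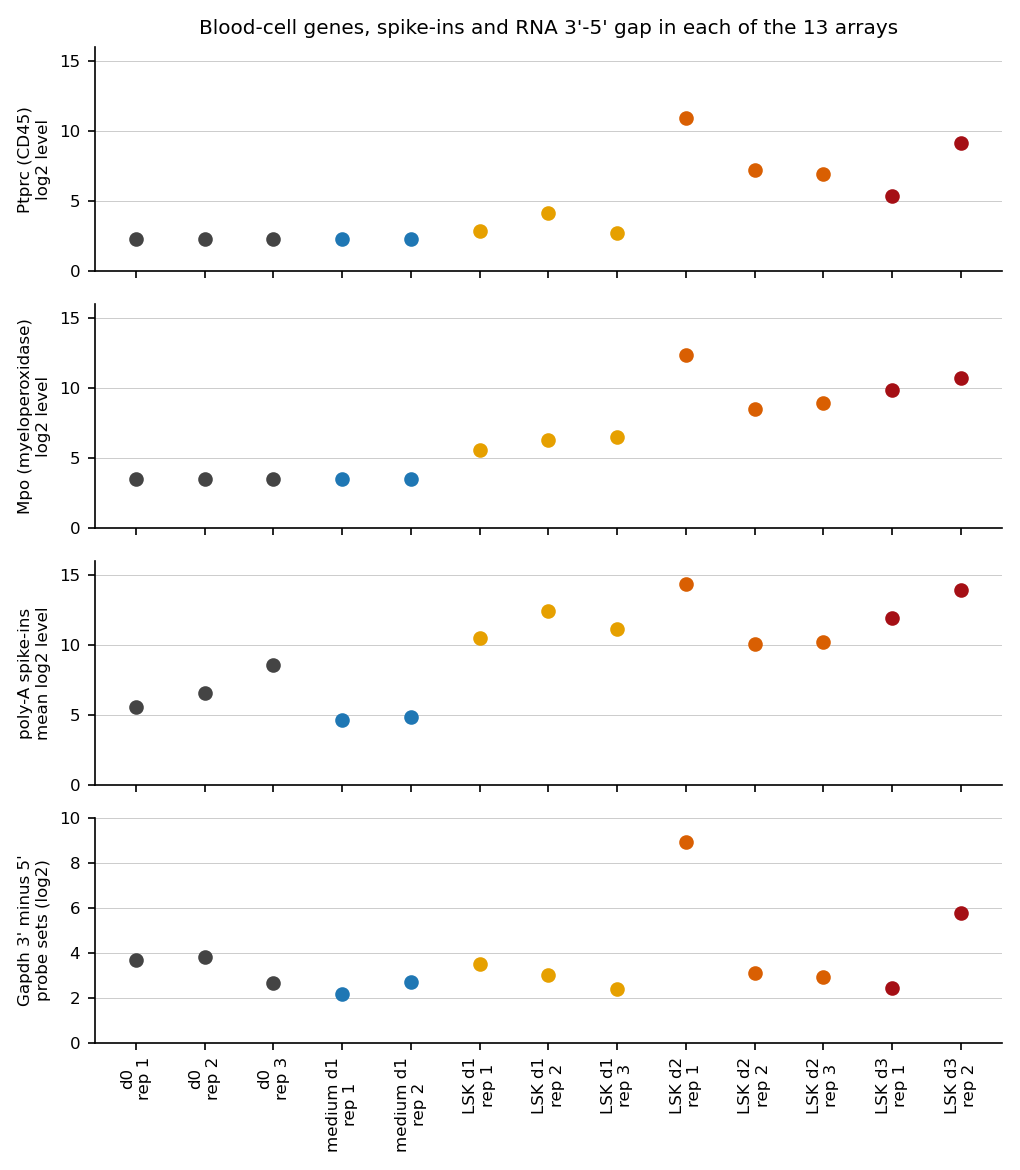
Log2 levels of Ptprc and Mpo, mean log2 level of the poly-A spike-ins and log2 gap between 3' and 5' Gapdh probe sets, with 1 point per array and colours marking the 5 groups. Ptprc lies at 2.28 on all day 0 and medium arrays and reaches 10.93 on day 2 replicate 1, where the Gapdh gap is 8.96.

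After 1 day with LSK cells, 4 of 49 measured proliferation genes fell past the threshold against the medium control, whose irradiation is not given. Pcna, the sliding clamp of DNA polymerase, fell from 13.37 ± 0.05 to 11.53 ± 0.31 (log2 change -1.84 ± 0.23, adjusted p = 0.0078). The mitotic motor Kif11 (-4.20 ± 1.03, adjusted p = 0.0483), the mitotic kinase Aurka (-2.80 ± 0.66) and the chromatin assembly factor Chaf1b (-2.58 ± 0.40) fell as well. Wnt2, a secreted Wnt ligand, rose from 2.74 ± 0.02 to 5.28 ± 0.22 (2.54 ± 0.26, adjusted p = 0.00298). The acute-phase gene Saa3 rose by 6.03 ± 1.32 (adjusted p = 0.037).

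The other 45 proliferation genes did not pass. The list's median change was -1.84 (camera, adjusted p = 7.02e-08), but adjusted p = 0.918 with an estimated correlation. Adjusted over the list alone, 13 members fell. With day 2 replicate 1 left out, which is not in this comparison, 18 fell past the threshold and 29 over the list alone. It was the single list of the 25 to pass in this comparison, and without day 2 replicate 1 myeloid genes passed too (median 0.34, adjusted p = 0.00699, and adjusted p = 0.743 with an estimated correlation). Single members of lists that did not pass also rose: Atf4, the transcription factor of the amino acid response, by 2.19 ± 0.49, the NF-kB inhibitor Nfkbia by 1.44 ± 0.35, Ifi35 by 2.09 ± 0.39 and the p53 target Bbc3 by 1.41 ± 0.19. Their lists, in this order, had 2 of 35, 2 of 28, 1 of 30 and 1 of 32 measured members higher past the threshold and 0 lower, and without day 2 replicate 1 they had 2, 3, 2 and 2 higher and 3, 1, 1 and 1 lower. In the protease list the urokinase receptor Plaur rose by 2.27 ± 0.37 and Mmp23 by 2.54 ± 0.59. The matrix glycoprotein gene Thbs2 rose by 1.78 ± 0.43, and Col11a1 fell by at least 1.04 to the lowest value. Among niche factors Igf1 fell by 3.40 ± 0.79 (adjusted p = 0.0427).

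The largest other falls were Zfp185 (by at least 5.14 ± 0.60), Nop58 (-4.94), Hacd4 (-4.71), Armcx4 (-4.68), the RNA-binding protein gene Zfr (-4.63 ± 0.48), Cep83os (-4.60) and Dpysl3 (-4.19). Large rises also included the nuclear receptor gene Esrra (4.34), Slc35e4 (4.14), Rpusd2 (3.98), Dgkz (3.88) and Yipf2 (3.75). The ubiquitin ligase gene Cblb (4.98) and the blood transcription factor gene Runx1 (3.21) rose in the tested probe set, while other probe sets gave 0.53 and -2.14 for Cblb and -1.11 to 0.74 for Runx1. Ctsg, the neutrophil protease cathepsin G, rose from 2.90 ± 0.42 to 7.56 ± 0.43. The platelet integrin gene Itga2b was higher than in the medium control by 2.79 ± 0.37 and the pre-B cell gene Vpreb1 by 2.19 ± 0.46, but at day 0, without LSK cells, they lay at 7.29 to 7.91 and 3.54 to 4.65, nearer to co-culture (7.91 to 8.64 and 4.59 to 4.77) than to the medium control (5.25 to 5.70 and 2.28 to 2.66). Day 0 lay nearer to co-culture than to the medium control for 274 of the 635 genes that passed and for 14 of the 34 named ones. Besides these 2, the 14 were Cblb, Esrra, Yipf2, Zfp185, Nop58, Igf1, Ifi35, Thbs2, Col11a1, Mmp23, Chaf1b and Bbc3. For all 14 the medium control lay further from day 0 than the co-culture did, but for some by little. Bbc3 differed from day 0 by 0.66 in co-culture and -0.74 in the medium control, and Esrra by 2.08 and -2.26. Spike-in signal was also higher in the co-culture, at 11.38 against 4.79. Ccn2, a matricellular growth-factor modulator, differed by 0.22 ± 0.78 (adjusted p = 1). The niche chemokine Cxcl12 differed by -2.06 ± 0.72 (adjusted p = 0.136), the adhesion molecule Vcam1 by -2.45 ± 1.02 (0.205), the stem cell factor gene Kitl by -0.09 ± 1.77 and Mki67 by -3.57 ± 2.11 (0.401). Wnt5a (-0.33), Sfrp1 (-0.72), Cdkn1a (0.74), Col1a1 (0.17), Ptprc (0.94) and Cd34 (0.11) did not pass either.

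In limma 635 genes passed, 263 higher and 372 lower in co-culture, and 609 of these changed at least 2-fold. Under quantile normalization the split was 372 higher and 320 lower. The groups did not overlap for 62.5% of all genes, where chance gives 20%. The count was 22 and 7 without medium replicates 1 and 2, 114, 68 and 51 without day 1 replicates 1, 2 and 3, and 2103 without day 2 replicate 1, which enters through the shared spread. Without that array Cxcl12 and Vcam1 passed (adjusted p = 0.0453 and 0.00947), and no named call held under every removal of 1 of the 5 compared arrays.

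**Figure D2:**
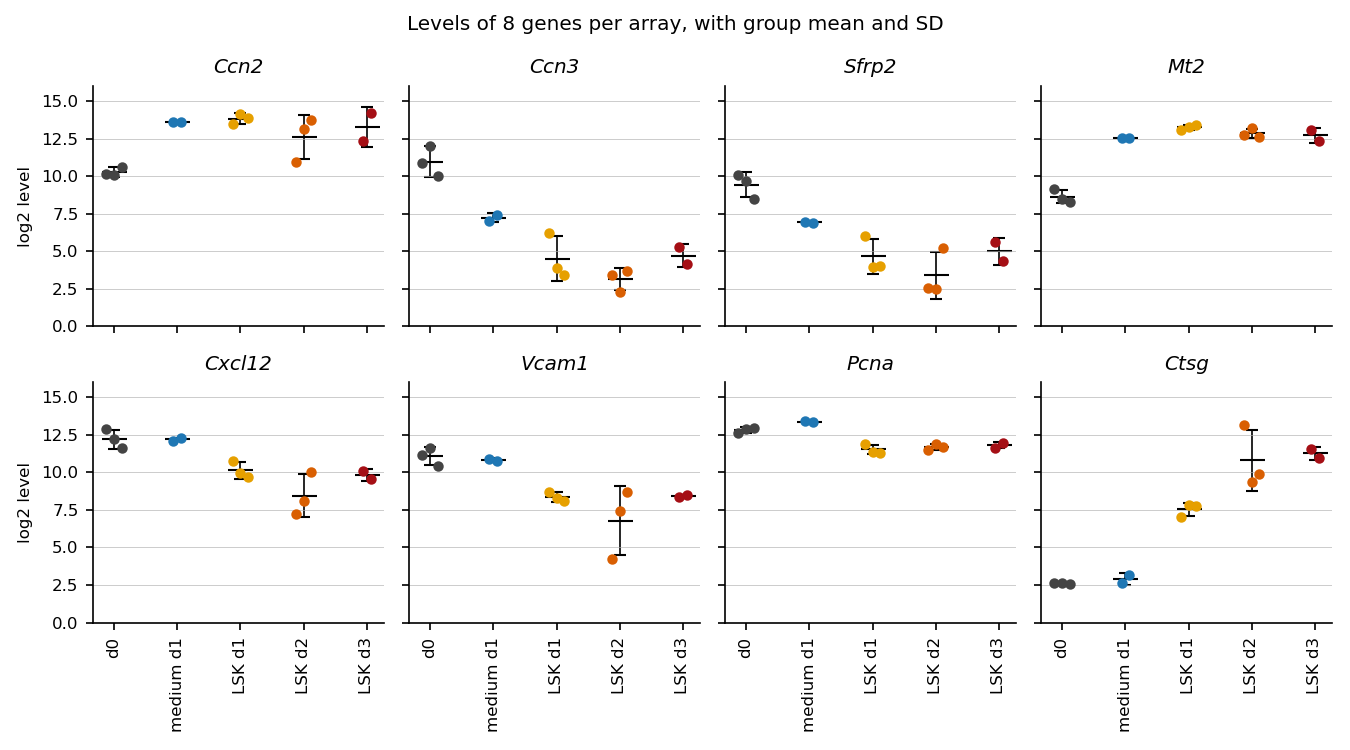
Log2 levels of Ccn2, Ccn3, Sfrp2, Mt2, Cxcl12, Vcam1, Pcna and Ctsg, with 1 point per array and bars for the group mean and SD. Mt2 lies at 8.62 at day 0 and at 12.54 in the medium control, and Pcna falls from 13.37 in the medium control to 11.53 on day 1 of co-culture.

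The medium control also differed from day 0 cells. The glucocorticoid-induced leucine zipper gene Tsc22d3 rose by 4.41 ± 0.64 (adjusted p = 0.0289) and Mt2, which encodes the metal-binding metallothionein 2, rose from 8.62 ± 0.44 to 12.54 ± 0.04 (3.92 ± 0.31, adjusted p = 0.00216). The insulin receptor substrate Irs2 rose by 3.13 ± 0.38, the spindle gene Ska1 by 2.61 ± 0.23, Klf13 by 2.59 ± 0.36 and Chaf1b by 2.67 ± 0.40. The thrombin receptor gene Thbd fell by 4.64 ± 0.73 (adjusted p = 0.0362), and the matrix genes Abi3bp (-4.29 ± 0.42, adjusted p = 0.00321) and Dcn, which encodes decorin (-2.34 ± 0.22, adjusted p = 0.00321), fell too. Further changes were in Zfp185 (3.71), Dus4l (2.67), Rerg (-3.94), Hoxb5os (-3.06), Lbh (-2.54), and Tbc1d24 (-2.01), Dnm3 fell by at least 1.96, and Col11a1 rose by at least 1.04.

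In this comparison 7 lists passed. Proliferation genes rose (median 0.81, adjusted p = 3.0e-05, but adjusted p = 0.893 with an estimated correlation), with 1 of 49 past the threshold, Chaf1b, and 1 adjusted over the list alone. Inflammatory genes fell (28 measured, median -0.69, adjusted p = 0.0114, and adjusted p = 0.374 with an estimated correlation), with 0 members past the threshold. Interferon genes fell (30 measured, median -0.38, adjusted p = 0.000514, and adjusted p = 0.554 with an estimated correlation), with 0 members and 2 adjusted over the list alone. Matrix proteases fell (19 measured, median -0.33, adjusted p = 0.0221, and adjusted p = 0.893 with an estimated correlation) with 0 members and 2 adjusted over the list alone, but not without day 0 replicate 2 (adjusted p = 0.0964). The p53 targets (median -0.51), smooth muscle genes (0.51) and oxidative stress genes (0.49) passed at adjusted p = 0.0491 each. With an estimated correlation they gave adjusted p = 0.893, 0.893 and 0.554. The last of these held 1 member past the threshold, Mt2, and 2 adjusted over the list alone, and the other 2 lists held 0 both ways. Without day 0 replicate 3, these 3 lists gave adjusted p = 0.052, 0.115 and 0.115, and most other single arrays also ended the calls. Leaving out day 2 replicate 1 put 1 inflammatory and 2 oxidative stress genes higher past the threshold, and 2 interferon, 1 protease and 1 p53 gene lower.

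In limma 40 genes passed, 27 higher and 13 lower, each at least 2-fold, and 43.3% of genes had no overlap, where chance gives 20%. The count was 137, 11 and 17 without day 0 replicates 1, 2 and 3, 8 without either medium array and 166 without day 2 replicate 1. Centring on measured probe sets left 2 higher and 2 lower. Of 17 named calls, Mt2 and Ska1 held without each of the 5 compared arrays. Ccn2 stood at 13.61 ± 0.01 against 10.27 ± 0.31 at day 0 (3.34 ± 0.78, adjusted p = 0.155, and 0.0206 without day 2 replicate 1). Ccn3, also of the CCN family, differed by -3.75 ± 0.87 (0.155). Cxcl12 (-0.03), Vcam1 (-0.26), Kitl (-1.86), Wnt5a (-0.57), Sfrp1 (-1.46), Mki67 (1.24), Cdkn1a (-0.53), Col1a1 (-0.31) and Cd34 (-0.88) did not pass, and Ptprc was at the lowest value in both groups.

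After 1 day with LSK cells Ccn2 was higher than at day 0, at 13.83 ± 0.36 against 10.27 ± 0.31 (3.56 ± 0.70, adjusted p = 0.0391), but the medium control without LSK cells lay at 13.61 as well. Of the 31 named calls here, 21 differed from day 0 in the medium control in the same direction by over 50% as much. Among them were Sphk1 (5.04), Prg4 (4.65), Tgm2 (3.05), AW551984 (-3.87), Ccn3 (-3.75) and Sfrp2 (-2.50), none of which passed there. Both comparisons share the day 0 arrays, which favours such agreement, and no value for unchanged groups was computed. Ccn3, a relative of Ccn2, was lower on day 1 of co-culture, at 4.51 ± 1.5 against 10.97 ± 1.02 (-6.46 ± 0.78, adjusted p = 0.00934). The metallothioneins Mt2 (4.63 ± 0.28, adjusted p = 0.000324) and Mt1 (2.47 ± 0.31) rose, as did Wnt2 (2.59 ± 0.24, adjusted p = 0.00228) and the sphingosine kinase gene Sphk1 (7.28 ± 1.56, adjusted p = 0.0495). The secreted Wnt antagonist Sfrp2 fell by 4.75 ± 0.84 (adjusted p = 0.0298), and the matrix genes Fbn2, Dcn and Abi3bp fell by 3.62 ± 0.51, by 2.61 ± 0.20 and by at least 4.62. Other large changes were in the lubricin gene Prg4 (5.35), Ctsg (4.96), the transglutaminase gene Tgm2 (4.40), Tsc22d3 (3.65), Zbtb7c (2.92), AW551984 (-6.77), Rerg (-4.45), Thbd (-4.43), Rps6ka6 (-4.04) and Zfr (-3.82). Bmp6 (-2.42 ± 0.45), Krt19 (-2.30 ± 0.44), Plaur (2.34 ± 0.33) and the fatty acid binding protein gene Fabp4 (2.52 ± 0.36) also passed.

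In total 5 lists passed, each with adjusted p = 0.992 with an estimated correlation. Niche factors fell (31 measured, median -1.0, adjusted p = 0.0158) with 0 members past the threshold either way and adjusted p = 0.0529 without day 2 replicate 1. Interferon genes fell (30 measured, median -0.40, adjusted p = 0.0158), with 3 members down, Irgm1 (-2.25), Ifit2 (-1.89) and Ifit3 (-0.73), and 6 adjusted over the list alone. Proliferation genes fell (49 measured, median -0.99, adjusted p = 0.0158) with 1 member, Pcna (-1.28 ± 0.21), and 1 adjusted over the list alone, but adjusted p = 0.323 without day 1 replicate 3. The unfolded protein and amino acid list rose (35 measured, median 0.46, adjusted p = 0.0199), with the serine synthesis gene Phgdh (2.15 ± 0.29) and Cebpb (1.19 ± 0.23) up and Herpud1 (-1.18 ± 0.20) down, the same counts adjusted over the list alone. It gave adjusted p = 0.0911 without day 1 replicate 2 and 0.0846 without day 2 replicate 1. Myeloid genes rose (20 measured, median 0.31, adjusted p = 0.0247) with 1 member, Ctsg, and 1 adjusted over the list alone, but adjusted p = 0.0893 and 0.0506 without day 1 replicates 2 and 3. Leaving out day 2 replicate 1 put 1 niche gene higher and 7 lower past the threshold (9 lower over the list alone), 5 interferon and 7 proliferation genes lower, 2 unfolded protein genes higher and 2 lower, and 5 myeloid genes higher.

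In limma 263 genes passed, 101 higher and 162 lower, 253 of them at least 2-fold, and 39.0% of genes had no overlap, where chance gives 10%. Under quantile normalization the split was 154 higher and 145 lower, and centring on measured probe sets moved the median of all genes from 0 to 0.15. The count was 115, 56 and 138 without day 0 replicates 1, 2 and 3, 42, 9 and 14 without day 1 replicates 1, 2 and 3, and 1290 without day 2 replicate 1. Of 31 named calls, those of Mt2, Abi3bp, Rerg, Wnt2 and Dcn held without each of the 6 arrays, while that of Ccn2 reached adjusted p = 0.153. Cxcl12 differed by -2.09 ± 0.65 (adjusted p = 0.131), Vcam1 by -2.71 ± 0.91 (0.159), Kitl by -1.95 ± 1.58 (0.637) and Mki67 by -2.33 ± 1.88 (0.636). The first 3 of these, without day 2 replicate 1, gave adjusted p = 0.0419, 0.00572 and 0.0342. Sfrp1 (-2.18), Wnt5a (-0.90), Cdkn1a (0.21), Col1a1 (-0.14), Ptprc (0.94) and Cd34 (-0.77) did not pass.

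The medium control and day 1 of co-culture shared 12 genes called in the same direction against day 0. Klf13, Fabp5, Srm, Mt2 and Tsc22d3 rose in both, and Abi3bp, Dcn, Dnm3, Gpr146, Qpct, Rerg and Thbd fell in both. Lists of these sizes drawn independently would share 0.223 rising and 0.173 falling genes. None of the 12 passed in co-culture against medium, where adjusted p ran from 0.23 to 1. There were 52 shared genes and 9 with opposite directions without day 2 replicate 1. The log2 changes of all genes had a covariance of 0.108, against a mean of 0.0543 and a highest value of 0.0600 in 100 simulations of unchanged groups with the same day 0 arrays. Their correlation across genes was 0.154, against 0.448 in the simulations. These simulations drew the noise of each gene independently, so noise that genes share on an array was left out. Simulated lists of the same sizes, taken by rank of p in a test chosen later, shared 12.5 genes on average and at most 18. Genes of the simulated lists need not pass the threshold, so this cannot tell whether the day 0 arrays alone would give 12 shared calls. The 3 day 0 arrays could not be split into parts of at least 2. Split into 1 and 2, in a test also chosen later, so that the comparisons shared no control, the 6 ways gave covariances from -0.229 to 0.161 with a mean of 0.0238, and 0 to 10 shared calls in the same direction against 0 to 13 in opposite directions. Part or all of the excess may thus come from the shared arrays. Of the 40 genes called in the medium control, 20 had the same sign in co-culture, and of the 263 called in co-culture 182 had the same sign in the medium control.

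**Figure D3:**
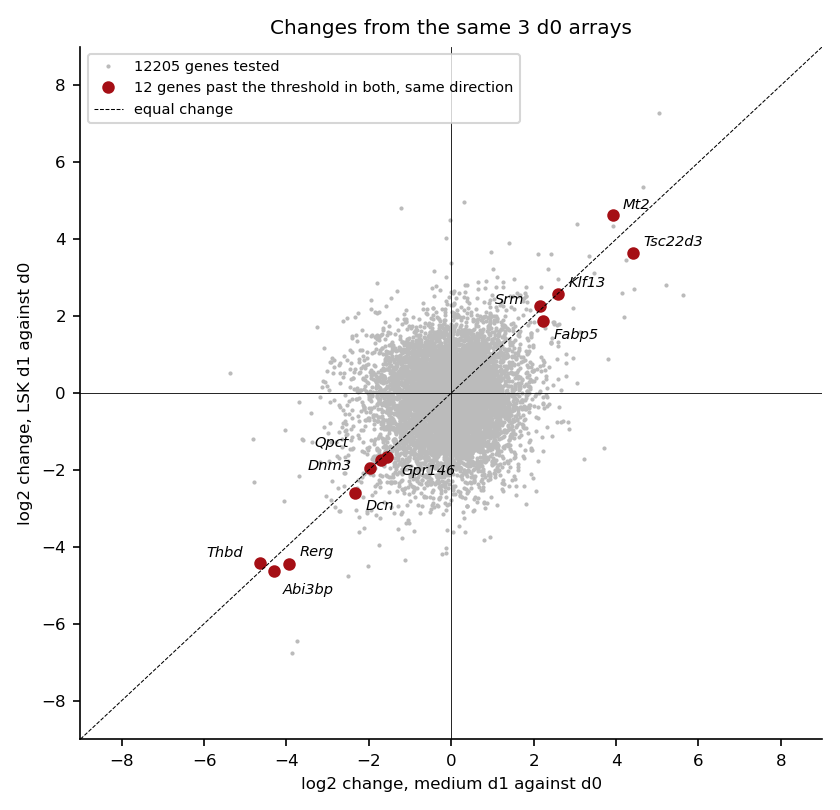
Log2 change of each of the 12205 genes from day 0 to the medium control (horizontal) and to day 1 of co-culture (vertical), with the dashed line marking equal changes. The 12 named points passed the threshold in both comparisons and lie near that line, from Thbd (-4.64 and -4.43) to Mt2 (3.92 and 4.63).

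After 2 days with LSK cells, 4 of 31 measured niche genes and 3 of 40 matrix genes fell past the threshold against day 0, and 5 of 20 myeloid genes rose. Cxcl12 fell from 12.22 ± 0.64 to 8.44 ± 1.43 (-3.78 ± 0.65, adjusted p = 0.0289), Vcam1 from 11.07 ± 0.59 to 6.79 ± 2.31 (-4.29 ± 0.91, adjusted p = 0.0478), the Notch ligand Jag1 by 3.54 ± 0.72 and the growth factor Fgf7 by 2.92 ± 0.61. Ccn3 fell by 7.84 ± 0.78 (adjusted p = 0.00406), the R-spondin gene Rspo2 by 6.46 ± 1.30 and Sfrp2 by 6.02 ± 0.84. The matrix gene Tnc fell by 5.15 ± 1.10, Fbn2 by 4.36 ± 0.51 and Dcn by 2.5 ± 0.20. Ctsg rose by 8.21 ± 0.81 (adjusted p = 0.00406) and Ptprc by at least 6.07 ± 1.15 (adjusted p = 0.0371). The Gapdh gap and spike-in signal were highest in this group on replicate 1. In the medium control, without LSK cells, Ccn3 (-3.75), Sfrp2 (-2.50), Dcn (-2.34), Fbn2 (-2.25) and Rspo2 (-2.03) also lay below day 0. Tnc (-0.64), Fgf7 (-0.55), Jag1 (-0.55), Vcam1 (-0.26), Cxcl12 (-0.03) and Ctsg (0.31) moved less there, and Ptprc stayed at the lowest value. No medium control was matched to day 2, so time in culture was not separated from co-culture.

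On day 2, 8 lists passed, and the median of all genes was itself -0.29. That median was -0.03 after quantile normalization, -0.47 after median centring and 0.44 after centring on measured probe sets. Relative to it, niche factors lay at -1.67, matrix genes at -1.26, proteases at -1.67 and p53 targets at -1.09. The unfolded protein list lay at 0.48, stem and progenitor genes at 2.37, myeloid genes at 4.03 and erythroid and megakaryocyte genes at 2.07. Niche factors fell (31 measured, median -1.96, adjusted p = 0.000432, and adjusted p = 0.525 with an estimated correlation), 4 of them past the threshold and 14 adjusted over the list alone, but with a median of -1.27 and 2 lower and 1 higher past the threshold without day 2 replicate 1. Matrix genes fell (40 measured, median -1.55, adjusted p = 6.33e-06, and adjusted p = 0.525 with an estimated correlation), with 3 down and 19 adjusted over the list alone. Proteases fell (19 measured, median -1.96, adjusted p = 0.00546, and adjusted p = 0.617 with an estimated correlation), with Adamts5 (-4.16), Mmp2 (-2.05) and Ctsb (-1.15) down, and 8 down and 1 up adjusted over the list alone, but with a median of -0.98 and 0 members past the threshold without day 2 replicate 1. The p53 targets fell (median -1.38, adjusted p = 0.0281, and adjusted p = 0.673 with an estimated correlation) with 0 members either way, and gave adjusted p = 0.3 (median -0.25) without day 2 replicate 1 and 0.0968 without day 0 replicate 1. Proliferation genes did not pass, but fell without day 2 replicate 1 (median -1.29, adjusted p = 0.000912, and adjusted p = 0.763 with an estimated correlation).

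Stem and progenitor genes rose (25 measured, median 2.08, adjusted p = 6.04e-08, and adjusted p = 0.525 with an estimated correlation), with Laptm5 (7.0) and Ptprc past the threshold and 6 adjusted over the list alone. Day 2 replicate 1 carried most of this size, and without it the median was 0.36 (adjusted p = 0.000529, and adjusted p = 0.656 with an estimated correlation), with 2 members higher and 1 lower. Myeloid genes rose (20 measured, median 3.75, adjusted p = 5.66e-12, and adjusted p = 0.525 with an estimated correlation), 5 past the threshold and 9 adjusted over the list alone, among them Tyrobp (at least 7.47), Prtn3 (6.55) and Srgn (6.52). The myeloid median was 1.12 without day 2 replicate 1, under that of day 3, with adjusted p = 7.86e-11, adjusted p = 0.0227 with an estimated correlation, and 7 members past the threshold. Erythroid and megakaryocyte genes rose (8 measured, median 1.78, adjusted p = 0.00116, and adjusted p = 0.525 with an estimated correlation) with 0 members either way, and gave adjusted p = 0.108 (median 0.26) without day 2 replicate 1. Unfolded protein and amino acid genes rose (median 0.19, adjusted p = 0.011, and adjusted p = 0.525 with an estimated correlation) with 1 member, Phgdh (1.82), and 6 up and 2 down adjusted over the list alone, but adjusted p = 0.126 without day 2 replicate 2, and a median of 0.42 without day 2 replicate 1. Outside the lists, the macrophage lectin gene Chil3 (at least 9.15), Cytip (7.55) and AI662270 (6.95) rose, and AW551984 (-7.02), Olfml3 (-5.49), Fat4 (-5.09) and Npr3 (-4.89) fell. Mt2 rose by 4.23 ± 0.28, Mt1 by 2.55 ± 0.31 and Fabp4 by 1.99 ± 0.36. In the medium control Mt2 (3.92), Mt1 (1.76) and Fabp4 (1.83) lay above day 0 too. Catalase (Cat) rose by 0.85 ± 0.18 in the tested probe set, while its other probe set gave -1.41. Bmp6 (-2.59), Irgm1 (-2.08), Ifit3 (-0.72, but 0.01 after centring on measured probe sets), Krt19 (-2.20), Aurka (-2.74) and Pcna (-1.12) fell. Of these, Bmp6 (-1.84), Irgm1 (-1.76), Ifit3 (-0.75) and Krt19 (-1.45) lay below day 0 in the medium control too. Aurka (0.32) and Pcna (0.56) lay above it there.

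In limma 276 genes passed on day 2, 78 higher and 198 lower, 265 of them at least 2-fold, and 22.7% of genes had no overlap, where chance gives 10%. The split was 105 higher and 123 lower under quantile normalization and 53 and 69 after centring on measured probe sets. The count was 60, 26 and 125 without day 0 replicates 1, 2 and 3, and 303, 32 and 3497 without day 2 replicates 1, 2 and 3. Of the 276 genes 170 were among the 303. Without replicate 1, Cxcl12 (-3.16, adjusted p = 0.0388), Vcam1 (-3.0, 0.015) and Ptprc (at least 4.79, 0.0409) passed, and Jag1 (0.0509), Fgf7 (0.0668) and Adamts5 (0.0778) did not. Replicate 2 also had a low median level over the tested genes, 6.61, against 7.51 on replicate 3 and 5.69 on replicate 1. With replicate 1 kept, the calls of Cxcl12, Vcam1 and Ptprc were lost without replicate 2, as they were without day 0 replicate 1 or 2. Of 37 named calls, those of Ctsg, Ccn3, Fbn2, Dcn, Mt2 and Mt1 held without each of the 6 arrays. Ccn2 differed by 2.33 ± 0.70 (adjusted p = 0.0956, and 0.0243 without replicate 1), Sfrp1 by -6.05 ± 1.70 (0.0852), Wnt5a by -3.20 ± 1.20 (0.143), Kitl by -3.60 ± 1.58 (0.185) and Col1a1 by -1.76 ± 0.47 (0.0766). Mki67 (0.09), Cdkn1a (-0.83) and Cd34 (1.05) did not pass. Replicate 1 carried much of these values: with it left out Wnt5a differed by -1.43, Kitl by -1.27, Mki67 by -2.35, Cdkn1a by 0.09 and Cd34 by -0.71.

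On day 3, the largest rises over day 0 were in blood-cell genes. Chil3 rose by at least 9.12 ± 1.52 (adjusted p = 0.0379), Ctsg by 8.68 ± 0.91 (adjusted p = 0.00874), the lysosomal protease gene Ctss by 7.08 ± 1.04, Tyrobp by at least 7.06 ± 1.32, the macrophage gene Mpeg1 by at least 6.90 ± 0.99 and Mpo by at least 6.75 ± 0.93 (adjusted p = 0.0233). Laptm5 (6.88) and Prtn3 (6.47) rose as well. Among stromal genes Ccn3 fell by 6.26 ± 0.87 (adjusted p = 0.0233), Abi3bp by at least 4.62, Fbn2 by 4.06 ± 0.57, Thbd by 4.12 ± 0.73 and Dcn by 2.52 ± 0.22. Zfp874a (-4.13), Ccser2 (-4.13), Klhl42 (-4.11), Rerg (-3.78) and Irgm1 (-2.32) fell as well. Mt2 rose by 4.09 ± 0.31 (adjusted p = 0.00277), Mt1 by 2.37, Phgdh by 1.88 and Fabp4 by 2.27. In the medium control, without LSK cells, Ccn3 (-3.75), Abi3bp (-4.29), Fbn2 (-2.25), Thbd (-4.64) and Dcn (-2.34) also lay below day 0. So did Rerg (-3.94) and Irgm1 (-1.76), while Mt2 (3.92), Mt1 (1.76), Phgdh (1.90) and Fabp4 (1.83) lay above it. Zfp874a (-1.09), Ccser2 (-0.92) and Klhl42 (0.77) moved less there, and the blood-cell genes by -0.47 to 0.31. No medium control was matched to day 3, so time in culture was not separated from co-culture.

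On day 3, 6 lists passed. Myeloid genes rose (20 measured, median 2.91, adjusted p = 3.85e-11, and adjusted p = 0.68 with an estimated correlation), 5 past the threshold and 10 adjusted over the list alone. Stem and progenitor genes rose (25 measured, median 1.12, adjusted p = 4.69e-05, and adjusted p = 0.68 with an estimated correlation), with Laptm5 past the threshold and 7 up and 1 down adjusted over the list alone. The unfolded protein list rose (35 measured, median 0.49, adjusted p = 0.0112, and adjusted p = 0.68 with an estimated correlation), with Phgdh past the threshold and 2 adjusted over the list alone. Matrix genes fell (40 measured, median -0.65, adjusted p = 0.0112, and adjusted p = 0.738 with an estimated correlation), with Fbn2 and Dcn past the threshold and 2 adjusted over the list alone. Niche factors fell (31 measured, median -0.76) and Wnt genes fell (36 measured, median -0.70), each at adjusted p = 0.0221, and adjusted p = 0.738 with an estimated correlation, with 0 members past the threshold. Adjusted over the list alone, 0 niche genes and 1 Wnt gene fell. Without day 3 replicate 2 the unfolded protein, matrix, niche and Wnt lists gave adjusted p = 0.5, 0.174, 0.121 and 0.451. Niche factors gave 0.096 without day 3 replicate 1, and matrix genes 0.102 without day 0 replicate 2. Erythroid and megakaryocyte genes also passed without day 2 replicate 1 (median 0.82, adjusted p = 0.0415, and adjusted p = 0.261 with an estimated correlation), and with that array left out myeloid genes gave adjusted p = 0.00395 with an estimated correlation. Members past the threshold were then 13 myeloid genes higher, 9 stem and progenitor genes higher and 1 lower, 3 unfolded protein genes higher and 2 lower, and 4 matrix, 2 niche and 3 Wnt genes lower.

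In limma 100 genes passed on day 3, 43 higher and 57 lower, 98 of them at least 2-fold, and 35.6% of genes had no overlap, where chance gives 20%. Median centring gave 31 higher and 27 lower, and centring on measured probe sets moved the median of all genes from 0 to 0.20. The count was 55, 4 and 55 without day 0 replicates 1, 2 and 3, 226 and 33 without day 3 replicates 1 and 2, and 939 without day 2 replicate 1. Of 22 named calls, those of Abi3bp, Zfp874a, Dcn and Mt2 held without each of the 5 arrays. Ptprc differed by 4.98 ± 1.29 (adjusted p = 0.125), Ccn2 by 3.00 ± 0.78 (0.128), Cxcl12 by -2.39 ± 0.72 (0.177), Vcam1 by -2.65 ± 1.02 (0.284) and Col1a1 by -1.77 ± 0.53 (0.176). Without day 2 replicate 1 these gave adjusted p = 0.0195, 0.0134, 0.0458, 0.0114 and 0.0422. Kitl (-1.21), Sfrp1 (-3.60), Wnt5a (-1.61), Mki67 (1.04), Cdkn1a (-0.34) and Cd34 (0.01) did not pass. Day 3 replicates 1 and 2 lay far apart for some of these, with Mki67 at 6.84 and 10.66 and Sfrp1 at 11.30 and 6.35.

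**Figure D4:**
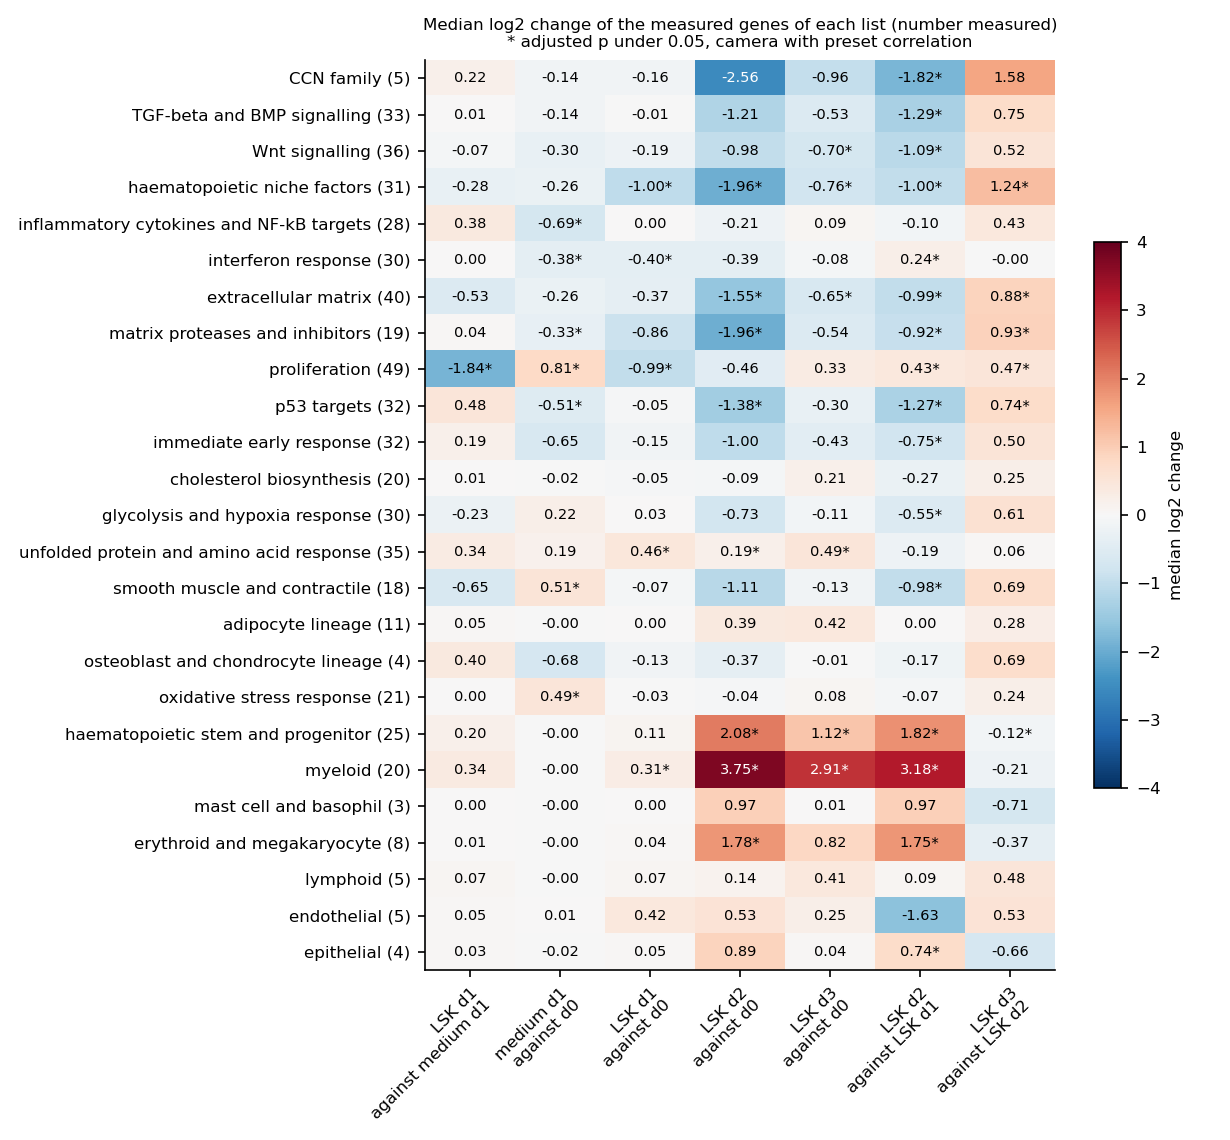
Median log2 change of the measured genes of each of the 25 lists (vertical, number measured in brackets) in the 7 comparisons (horizontal), in colour from -4 to 4 with the value in each cell. Asterisks mark an adjusted p under 0.05 by camera with a preset correlation, which 49 tests reached, and the myeloid list has the highest median, 3.75 on day 2 against day 0, which is 1.12 without day 2 replicate 1.

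Between days of co-culture single genes hardly separated. Wnt2, which had risen on day 1, fell from 5.28 ± 0.22 on day 1 to 3.02 ± 0.48 on day 2 (-2.27 ± 0.24, adjusted p = 0.0431). It was the only gene to pass from day 1 to day 2 in limma, where 1541 genes had an unadjusted p under 0.05. Myeloid genes rose from day 1 to day 2 (median 3.18, adjusted p = 4.81e-13), as did stem and progenitor genes (1.82, adjusted p = 6.97e-10), while matrix genes fell (-0.99, adjusted p = 4.42e-05). With an estimated correlation these 3 lists did not pass, and without day 2 replicate 1 their medians were 0.96, 0.26 and -0.65. Ccn2 (-1.23), Cxcl12 (-1.69), Vcam1 (-1.57), Kitl (-1.65), Wnt5a (-2.29), Sfrp1 (-3.87), Mki67 (2.42), Cdkn1a (-1.04), Col1a1 (-1.62), Ptprc (5.13) and Cd34 (1.82) did not pass. Leaving out day 2 replicate 1 turned Kitl to 0.68 and Mki67 to -0.02, and gave -0.40 for Ccn2, -1.07 for Cxcl12, -0.29 for Vcam1, -0.53 for Wnt5a, -2.86 for Sfrp1, -0.12 for Cdkn1a and 0.06 for Cd34.

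From day 1 to day 2, 16 lists passed, with 1 single member past the threshold, Wnt2. Besides the 3 lists just named, the CCN family (-1.82), TGF-beta and BMP (-1.29), p53 (-1.27), Wnt (-1.09), niche (-1.0), smooth muscle (-0.98), protease (-0.92), immediate early (-0.75) and glycolysis genes (-0.55) fell. Erythroid (1.75), epithelial (0.74), proliferation (0.43) and interferon genes (0.24) rose. The median of all genes was -0.19, and 0.39 after centring on measured probe sets, where the glycolysis list turned to 0.03. Such centring moves all genes by the same amount, and relative to the median of all genes the glycolysis list stayed at -0.36. Adjusted over the list alone, 7 myeloid genes and 1 stem and progenitor gene rose, and 1 gene each of the Wnt, matrix, protease and immediate early lists fell. Adjusted p ran from 0.491 to 0.6 with an estimated correlation for all 16. Without day 2 replicate 1, the interferon, matrix, stem and progenitor and myeloid lists passed (adjusted p = 0.0441, 7.22e-05, 0.000236 and 6.06e-10) and the other 12 did not, and with an estimated correlation as well only the myeloid list did (adjusted p = 0.0291). The medians of the other 12 then ran from -1.20 (CCN family) to 0.04 (epithelial). The Wnt2 call was lost without that array (adjusted p = 0.058) and without each of the 3 day 1 arrays and day 2 replicate 2. The count was 1887 without day 2 replicate 3, and 1 gene other than Wnt2 passed without replicate 1. The groups did not overlap for 12.4% of genes, where chance gives 10%.

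From day 2 to day 3 limma called 0 genes, with 677 at an unadjusted p under 0.05, and 7.81% of genes had no overlap, where chance gives 20%. In this step 6 lists passed, each with 0 members past the threshold, 0 adjusted over the list alone, and adjusted p = 0.836 with an estimated correlation. Niche (median 1.24), protease (0.93), matrix (0.88), p53 (0.74) and proliferation genes (0.47) rose, and stem and progenitor genes fell (-0.12). The median of all genes was 0.21, and -0.32 after centring on measured probe sets, where proliferation turned to -0.06. Relative to all genes proliferation lay at 0.26 and stem and progenitor genes at -0.33, which centring leaves unchanged because it moves all genes equally. The stem and progenitor median turned to 0.02 after median centring, and the list rose without day 2 replicate 1 (0.84, adjusted p = 0.0093, and adjusted p = 0.787 with an estimated correlation). Without that array myeloid genes rose (1.33, adjusted p = 2.13e-11, and adjusted p = 0.0195 with an estimated correlation), as did proliferation genes (1.21, adjusted p = 3.83e-11, and adjusted p = 0.787 with an estimated correlation), each with 11 members adjusted over the list alone. Wnt genes fell (-0.21, adjusted p = 0.0283, and adjusted p = 0.787 with an estimated correlation), and the niche (0.39), protease (0.39), matrix (0.46) and p53 lists (0.17) no longer passed. The day 3 arrays differed in proliferation genes, with a median over day 0 of -0.51 on replicate 1 and 0.95 on replicate 2. With day 2 replicate 1 kept and day 3 replicate 2 left out, the proliferation median from day 2 to day 3 was -0.03. The counts were 4, 0 and 892 without day 2 replicates 1, 2 and 3, and 102 and 3 without day 3 replicates 1 and 2. Cxcl12 (1.39), Vcam1 (1.64), Kitl (2.39), Sfrp1 (2.46), Wnt5a (1.59), Ccn2 (0.67), Mki67 (0.95), Cdkn1a (0.49), Col1a1 (-0.01), Ptprc (-1.10) and Cd34 (-1.03) did not pass. With day 2 replicate 1 left out these 11 gave 0.77, 0.36, 0.06, 1.45, -0.18, -0.17, 3.39, -0.43, -0.46, 0.19 and 0.73, in this order.

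Cholesterol biosynthesis, adipocyte, osteoblast and chondrocyte, mast cell, lymphoid and endothelial genes passed in no comparison. Their lowest adjusted p-values over the 7 comparisons were 0.341, 0.0677, 0.159, 0.184, 0.28 and 0.451.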

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

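All tests on day 2 replicate 1, the sign test of the spike-ins and the test along the day 0 arrays were chosen only after the results were seen. So were the test by ranked lists and the split of the day 0 arrays. The covariance test of the shared day 0 arrays and the splits of samples were chosen before.

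Day 2 replicate 1 stood apart, with a Gapdh 3' minus 5' gap of 8.96, above every control array. No tested explanation was excluded. Day 2 of co-culture as such cannot be told apart from the others: its highest correlation of levels with the other day 2 arrays, 0.73, lay 0.195 below their own 0.925, but this array was singled out by such low correlations, and its changes over day 0 correlated at 0.459 with the mean of the other 2, which correlated at 0.496 with each other. Besides, blood-cell RNA may have been harvested with the stroma, as no step that removes LSK cells is given. On this array 45 blood markers, among them Ctsg at 13.14, Tyrobp at 12.70 and Mpo at 12.36, rose a median of 6.41 more than 9 endothelial and epithelial markers. Those 9 did not move alike, with a median from day 0 of -1.96 for endothelial and 1.68 for epithelial markers. Of the 45 blood markers 9 lay above 5 at day 0, so most had little room to fall. Ptprc and Mpo lay above their lowest values on every other co-culture array too, so this is not limited to replicate 1. Dilution by such RNA would lower all genes read only from stroma by the same factor. On the 3 day 1 arrays the median of 40 matrix genes lay at -0.05, -0.50 and -0.71 from day 0. Of the 162 genes that fell past the threshold on day 1 against day 0, 158 fell at least 2-fold. These values argue against dilution alone for those 158 falls. Smaller falls, and falls on days 2 and 3, were not separated from dilution. Little or degraded RNA could account for a gap 5.98 above the median of the others.

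The medium control and day 1 of co-culture shared 12 calls against day 0. No tested explanation was excluded. The shared day 0 arrays cannot be told apart from a shared response for these 12. The covariance over all genes, 0.108, exceeded the highest simulated 0.0600 and so met the bound written against this explanation. That bound cannot exclude the shared arrays, since the simulations drew the noise of each gene independently and left out noise that genes share on an array. It also did not cover the called genes. Simulated lists of the same sizes shared 12.5 genes on average and at most 18, but their genes need not pass the threshold, so they do not decide it for calls. With the day 0 arrays split into 1 and 2 the covariance ran from -0.229 to 0.161. All 12 moved in the same direction, while spike-in signal, whose added amounts are not given, moved in opposite directions in the 2 groups, but the shared day 0 arrays push such genes to 1 direction: in the simulated lists 98.4% of shared genes agreed on average. For the 40 genes called in the medium control RNA input cannot be told apart from other causes, since a share of 0.5 kept their sign in co-culture, as did 182 of the 263 co-culture calls in the medium control. These shares too are affected by the shared day 0 arrays, and no value for unchanged groups was computed for them. A response to the medium, which both groups may have received, was untested.

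Day 1 of co-culture differed from the medium control in 635 genes, so their change against day 0 differed between these groups. No tested explanation was excluded, and an effect of LSK cells themselves stayed open as well, untested. Whether the medium control was irradiated like the co-cultured stroma is not given, so a difference in irradiation was not separated either. An axis already present among the day 0 arrays cannot be told apart from the difference of the groups: a share of 0.783 of these genes differed in the matching direction between day 0 replicate 1 and replicates 2 and 3, but replicate 1 was picked because it lay nearest to the medium arrays, which favours that outcome. The median size along that axis was 0.45 against 1.98, and 538 of the 635 genes changed by over 2 times their difference along it. RNA input cannot be told apart from co-culture, because spike-in signal nearly follows the groups. With it as a covariate the median change kept a share of 0.86 of its size (1.98 to 1.71). In that fit 0 genes passed, and the median standard error of a gene rose from 0.383 to 0.696, a share of 0.351 of the median change. The share of 0.86 met the bound written against this explanation, 0.75, but by less than that standard error of a single gene. This condition was applied after the value was seen, and the spread of the share over the 635 genes as a set was not computed.

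From day 1 to day 2, the change against day 0 differed for 1 gene, Wnt2. Spike-in signal exceeded the highest control array, 8.62, in the means of days 1, 2 and 3, at 11.38, 11.55 and 12.96. Day 3 replicate 2 had a Gapdh gap of 5.79, above the highest control value of 3.82. For co-culture against day 0 and between days, 10 splits of 6 arrays are too few for a share under 0.05. The real counts were 263 on day 1, 276 on day 2 and 1 from day 1 to day 2, each 1 of the 10 splits, and the highest other split gave 0 in each case.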

How the results depend on the processing

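The filter above 5, centring on measured probe sets, the spike-in covariate and the removal of doubted arrays were chosen after seeing the data. Counts are given in the order day 1 against medium, medium against day 0, days 1, 2 and 3 against day 0, day 2 against day 1 and day 3 against day 2, where they differed by over 1.5 times from 635, 40, 263, 276, 100, 1 and 0. Except for the fits noted, the cause was not tested. Of 215 named results 142 passed; over 2858 alternatives 1797 kept direction and side, 1059 fell short and 2 reversed. Those 2 were Cat on day 2 as a mean of probe sets (-0.28) and Ifit3 on day 2 after centring on measured probe sets (0.012). The latter scaling moved all genes equally, their median from -0.29 to 0.44, so Ifit3 did not reverse relative to other genes. Of 1452 alternatives for the 73 others, 54 passed in the same direction and 105 turned sign without passing.

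Without a filter the counts were 162 and 106 for days 1 and 2, 0 for day 2 against day 1 and 11 for day 3 against day 2. The mean filter gave 0 for day 2 against day 1, as did quantile normalization, with 64 for day 3. Median centring gave 404, 24, 158, then 58 for day 3 and 0 for day 2 against day 1. Every probe set tested separately gave 1661, 277, 482, 465, 252, 0 and 1. An intensity trend with robust eBayes gave 152 for day 1 and 2 for day 3 against day 2. Array weights gave 6423, 3585, 3583, 2542, 167 and 1272, and 0 for the last. Fits of only the 2 groups compared, which leave the other arrays out of the spread, gave 4574, 83, 1786, 0, 26 and 0. The filter above 5 gave 385, 12, 108, then 41 for day 3 and 0 for day 2 against day 1. Centring on measured probe sets gave 350, 4, 128, 122, 34 and 0. The spike-in covariate gave 0, 11, 2, 1, 0 and 2. Leaving out day 2 replicates 1 and 2 and day 3 replicate 2, where the lone arrays are assumed to vary like other groups, gave 3770, 761, 2845, 177, 1727, 70 and 206.

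Without day 2 replicate 1 the counts were 2103, 166, 1290, 303, 939, 1 and 4. Leaving out each compared array in turn gave ranges of 7 to 114, 8 to 137, 9 to 138, 26 to 3497, 4 to 226, 0 to 1887 and 0 to 892. With the replicate number as a block the counts were 208, 8, 103, 26, 4, 0 and 0. The numbers gave no clear sign of pairing. Deviations from the group mean correlated at 0.003 on average between same-numbered arrays of different groups, over 0.1 in 8 of 23 pairs. Between different-numbered arrays the mean was -0.001, over 0.1 in 12 of 44 pairs. By these deviations 5 of 13 arrays correlated best with an array of their own number.

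Over the 25 lists and 7 comparisons 49 tests passed; 0 did with an estimated correlation, 4 with directional fry, 32 with mixed fry, 24 without the 3 doubted arrays and 33 to 51 with 1 array left out. With an estimated correlation and day 2 replicate 1 left out, 4 passed. The overlap of 12 genes became 52 without day 2 replicate 1.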

Other observations

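All tests in this part were chosen after the gene results were seen, and the bounds for the pair of gene lists below were written before their tests were run. None was written for the overlap of days.

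A set of 63 genes passed in the same direction on all 3 days of co-culture against the same day 0 arrays, 17 higher and 46 lower. The rises included the metallothioneins Mt1 and Mt2, the serine synthesis gene Phgdh, Fabp4, Ctsg, the mitochondrial ribosome gene Mrps17, the ubiquinone synthesis gene Coq4 and the folate carrier gene Slc19a1. The falls included Ccn3, the matrix genes Fbn2, Dcn and Abi3bp, the receptor tyrosine kinase inhibitor Spry1, the protocadherin Pcdh19, the splicing factor Sf3b1, the DNA repair gene Nbn, the repressor gene Rest and Zfr. Independent lists of these sizes would share 0.00227 rising and 0.0123 falling genes, and 100 simulations of unchanged groups against the same arrays, with lists of the same sizes by rank of p, shared 10.5 on average and at most 18. Some are not particular to co-culture: in the medium control 9 of the 63 were called in the same direction, among them Mt2, Dcn and Abi3bp. In that control 44 differed from day 0 in the same direction, and 23 did so by over 50% of the day 1 change. Among the 23 were also Phgdh (1.90), Fabp4 (1.83), Mt1 (1.76), Coq4 (1.23), Ccn3 (-3.75) and Fbn2 (-2.25). The shared day 0 arrays favour such agreement, and no value for unchanged groups was computed for the 44 and 23. How much of the excess came from the shared day 0 arrays could not be told, since the simulations drew the noise of each gene independently.

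Tsc22d3 and Mt2, which glucocorticoids induce, led to the hypothesis that glucocorticoid receptor targets may be higher after the change of medium. A list of 14 other targets, among them Mt1 (1.76), had a median change of 1.37 from day 0 to the medium control, with 10 of 14 higher. Camera gave adjusted p = 0.00115 over the 6 tests of this part, and adjusted p = 0.408 with an estimated correlation. In limma 0 members passed, and 4 did without day 2 replicate 1. Fkbp5 (4.23 ± 1.08, adjusted p = 0.19) and Zbtb16 (4.43 ± 1.06, adjusted p = 0.166) were among the highest. On day 1 of co-culture the median was 1.79, with 13 higher (adjusted p = 7.42e-05, and adjusted p = 0.408 with an estimated correlation), and between these groups it was 0.15 (adjusted p = 0.364). A glucocorticoid in fresh serum is a candidate source, but no hormone was measured.

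The rise of Ccn2 led to a further hypothesis, that targets of YAP and SRF, which respond to cell attachment, may be low in trypsinised day 0 cells. Of 20 listed targets without Ccn2, 17 were measured, 10 were higher in the medium control and the median change was 0.25. Camera gave adjusted p = 0.228, which decides nothing. On day 1 of co-culture the median was -0.56 against day 0 (adjusted p = 0.277) and -0.87 against the medium control (adjusted p = 0.0922). The latter, without day 2 replicate 1, gave adjusted p = 0.0408 with 3 members lower, and adjusted p = 0.605 with an estimated correlation.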
